A study of Mus musculus with 10 samples.

How the data were processed

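RNA was measured in 10 subcutaneous tumors of the mouse line B2905-M4, 5 with Adamts7 overexpression and 5 with a vector, and each tumor gave 1 library. Per the labels' protocols, spike-in RNA was added to the total RNA, messenger RNA was selected by its poly(A) tail, molecular identifiers were built into the cDNA primers, and paired reads of 150 bases were made on an Illumina instrument and demultiplexed with bcl2fastq 2.17. Whether the identifiers or the spike-ins were used in counting is not given in the sources used here. Each tumor's group was taken from its title. Tumors come from separate animals only as far as the design text speaks of tumors in mice. The p-values therefore measure the spread between these tumors and not between separately made cell populations.

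The expression table holds log2(TPM + 1) values that the authors deposited per gene symbol, with RSEM and the genome build mm39 named in the submitters' processing notes. Raising these log2 values back to TPM gave sums between 995286 and 998019 per tumor, so the table lacks a small part of each library. Because TPM is scaled within each library, a few very abundant genes lower all others, and the 10 most abundant genes took between 7.40% and 10.2% of the TPM of a tumor. TPM keeps no depth, and no interval from counting is given. RSEM divides reads between similar genes by estimate, so values of near-identical family members such as Tgtp1 and its neighbours are uncertain. The transcript annotation is not given in the sources used here. The reference in hand is of the older build GRCm38, so no coordinates are printed, and its names served only to pair gene identifiers with symbols, 28805 of 30040 of them.

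The authors' deposited comparison table gives a mean normalized signal, a log2 fold change with its standard error, a test score and a p-value before and after adjustment for each gene. DESeq2 is named in the submitters' processing notes, and the deposited score equals the log2 fold change over its standard error. The mean normalized signals deposited by the authors sum to a value that describes an average library and not any single tumor. The deposited repertoire table holds other measures by the authors, namely clone and clonotype numbers, entropy, clonality and isotype shares of antigen receptors, and no tool version is given for it in the sources used here. Those measures are not scaled to depth, so a deeper library could hold more clones. Isotype shares have a smaller denominator than the clone number beside them.

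Genes with a mean of at least 1 TPM over the 10 tumors were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with a pseudocount of 1 TPM, a trended prior variance, the group as the only term and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(TPM + 1) scale, which understates changes of low genes. Gene lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation beside it, and with fry, over the 42 of 44 lists that had at least 3 tested members; the B cell and keratinocyte lists had 2 and 1. Repertoire measures were compared by an exact two-sided permutation test over all arrangements of the tumors, with Benjamini-Hochberg adjustment over 20 measures. The arrangements were 5 against 5, but 4 against 5 for heavy chain entropy and clonality, which have no value in Adamts7 tumor 3. Python 3.11.15 and pandas 2.3.3 were used for the repertoire and for joining tables. The lists, tests, thresholds and rule for named genes were fixed before the data were examined. That rule names Adamts7, then up to 8 called genes with the largest and 8 with the smallest log2 fold change among those whose groups do not overlap, without predicted genes, clone names, pseudogenes and receptor segments, then up to 4 members of each list with the smallest p. Irgm1 was named by the list part of the rule.

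The gene test was tested on simulated data of 15276 genes with the spread of this comparison, in 10 runs with 200 changed genes. It recovered 50.3% of genes changed by 1 on the log2 scale, 83.0% of those changed by 2 and 95.2% of those changed by 3. There were 8 false calls per run. Genes were drawn independently, with the same spread in both groups. The recovery and the false calls may therefore differ in these tumors, where genes vary together. No pair of tumors had identical values. Alternatives tried were other pseudocounts, filters, scalings and variance models, tumor weights, a replicate block, each tumor left out in turn, all 100 possible choices of 3 against 3 tumors for the shared harvest day, and an estimated correlation for lists. Fits without vector tumors 3 and 5, and without these and the tumor labelled Adamts7 5, were added after the data were seen. Genes below the filter were left out of the main test.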

Results

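Bulk RNA sequencing was carried out on 10 subcutaneous tumors grown in female C57BL/6 mice from B2905-M4, a mouse melanoma cell line. Of these, 5 came from cells overexpressing Adamts7, a secreted metalloproteinase of the extracellular matrix, and 5 from cells carrying a vector control. The design text gives harvest at day 35 for 2 Adamts7 tumors, at day 45 for 3 tumors of each group and at day 50 for 2 vector tumors, and says that Adamts7 tumors grew faster. It ties no day and no size to a tumor, so results were also obtained for each of the 100 possible sets of 3 against 3 tumors of day 45. Tumor size could not be examined. Adamts7 was higher and the median of the genes induced by interferon-gamma was lower in all 100 sets. Expression was analysed as TPM, a transcript abundance scaled within each library that keeps no depth, so the read depth of each tumor is unknown. Between 21515 and 23859 of 29890 listed genes were above 0 TPM in a tumor, and 15276 genes with a mean of at least 1 TPM were tested.

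Adamts7 transcripts were higher on average in the Adamts7 tumors, and 1 tumor did not follow its group. Adamts7 was at 88.5, 96.0, 78.2 and 74.8 TPM in Adamts7 tumors 1 to 4 and at 18.2 TPM in the tumor labelled Adamts7 5. In the vector tumors it was at 6.49, 6.98, 28.3, 8.57 and 27.6 TPM, so that the tumor labelled Adamts7 5 lay below vector tumors 3 and 5. The group means were 71.2 ± 30.8 TPM (SD, n = 5) and 15.6 ± 11.3 TPM (SD, n = 5), a 4.57-fold ratio. The log2 fold change of Adamts7 was 2.21 with a standard error of 0.54, which did not pass the threshold over all genes (limma, adjusted p = 0.104). An exact two-sided permutation test of Adamts7 alone gave p = 0.0238. Without the tumor labelled Adamts7 5, the log2 fold change of Adamts7 was 2.64 with a limma adjusted p of 0.0238. Every difference below between the groups takes that tumor's label as given.

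**Figure D1:**
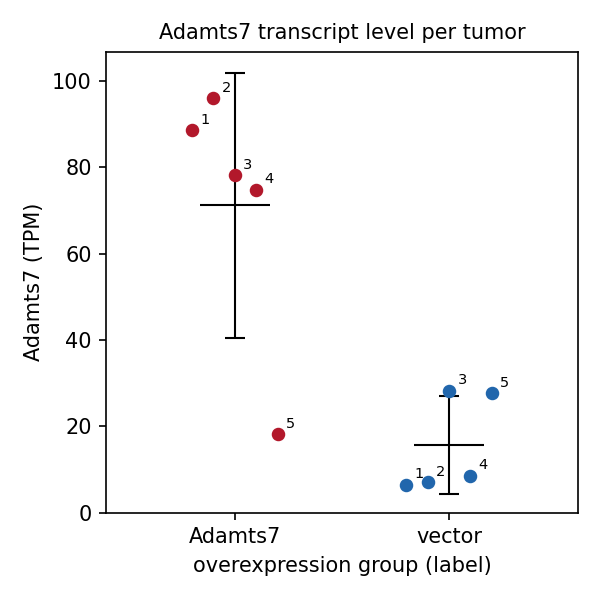
Adamts7 level in TPM (vertical axis) in each tumor of the 2 groups; points are tumors with their replicate numbers, and bars give the mean and SD of 5 tumors. The tumor labelled Adamts7 5, at 18.2 TPM, lies below vector tumors 3 and 5.

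Of the 15276 genes, 4 rose and 30 fell in Adamts7 tumors, and 4 of the 30 are in the list of genes induced by interferon-gamma. Gbp4, a guanylate-binding protein of cell-autonomous immunity, fell by 3.13 on the log2 scale (SE 0.52). The immunity-related GTPases Tgtp1, Iigp1 and Irgm1 had log2 fold changes of -2.66 (SE 0.37), -2.44 (SE 0.38) and -1.69 (SE 0.28). The protease inhibitor gene Serpina3f fell from 35.3 ± 27.6 to 2.84 ± 0.857 TPM, the imprinted gene Mest from 98.1 ± 60.6 to 15.1 ± 5.71 TPM, and the noncoding RNA gene Platr16 from 9.72 ± 3.27 to 1.06 ± 0.382 TPM (SD, n = 5 each). Ppp1r1c, a phosphatase inhibitor gene, and Tmem40 had log2 fold changes of -2.39 (SE 0.36) and -1.99 (SE 0.29). The 4 genes that rose were Gja3, a gap junction gene, Nptx1, a neuronal pentraxin, S100b, a calcium-binding protein of neural crest derivatives, and Zfhx4, a zinc finger homeobox gene. S100b rose from 72.0 ± 9.20 to 151 ± 28.9 TPM and Zfhx4 from 3.70 ± 1.04 to 8.53 ± 0.923 TPM, while Nptx1 rose from 0.986 ± 0.588 to 5.68 ± 1.99 TPM and Gja3 from 0.164 ± 0.190 to 4.49 ± 2.02 TPM (SD, n = 5 each).

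The limma adjusted p-values of these 13 named genes ran from 0.00906 for Platr16 to 0.0481 for Irgm1. All 34 called genes separated the groups without overlap, as did 747 of the tested genes, or 4.89%. Chance gives 0.794% as an average over all divisions of the tumors. Genes vary together, so a single division can lie far from that average, and the share was not computed for other splits. Under median-of-ratios scaling 10 genes rose and 20 fell, and quantile normalization gave the same 2 counts. Leaving out 1 tumor gave 15, 7, 6, 6 and 655 called genes for tumors labelled Adamts7 1 to 5, and 34, 42, 8, 6 and 6 for vector tumors 1 to 5; of the 13 named genes, Platr16 passed in all 10 of these fits and Zfhx4 in 1.

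The genes induced by interferon-gamma, the T cell cytokine, were lower as a group. All 15 tested members of this list had negative log2 fold changes with a median of -2.25; 4 fell over all genes tested, and 15 fell adjusted over the list alone. The list mean lay between 4.14 and 5.16 log2(TPM + 1) in the Adamts7 tumors and between 5.92 and 8.08 in the vector tumors. Genes of MHC class I antigen processing were also lower: 13 of 14 fell adjusted over the list alone, none over all genes, with a median log2 fold change of -1.34. Psmb9, an immunoproteasome subunit, was at 54.1 ± 11.4 against 179 ± 83.0 TPM, and the peptide transporter genes Tap1 and Tap2 were at 68.8 ± 17.3 against 182 ± 63.4 and 32.3 ± 8.24 against 85.9 ± 28.2 TPM (SD, n = 5 each). Limma camera with a preset correlation of 0.01 called both lists lower, with adjusted p-values of 1.6e-12 and 7.8e-08; both had an adjusted p = 0.63 with an estimated correlation. Fry, which asks whether a list's genes move one way, gave an adjusted p of 0.0392 for each of them and passed no other list. An exact permutation test of the list means, added after the data were seen, gave p = 0.00794 for each, the smallest that the arrangements of 5 against 5 allow, and 0.111 after adjustment over 42 lists. Without vector tumors 3 and 5, which stood apart from the other vector tumors, the list medians were -1.52 and -0.83 and the groups still did not overlap in either list mean. Neither list passed fry there (adjusted p = 0.0561 for each, and 0.0962 with the tumor labelled Adamts7 5 left out as well). Over the possible sets of day 45 the medians lay between -3.23 and -1.21 for the interferon-gamma list and between -1.83 and -0.62 for the MHC class I list.

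**Figure D2:**
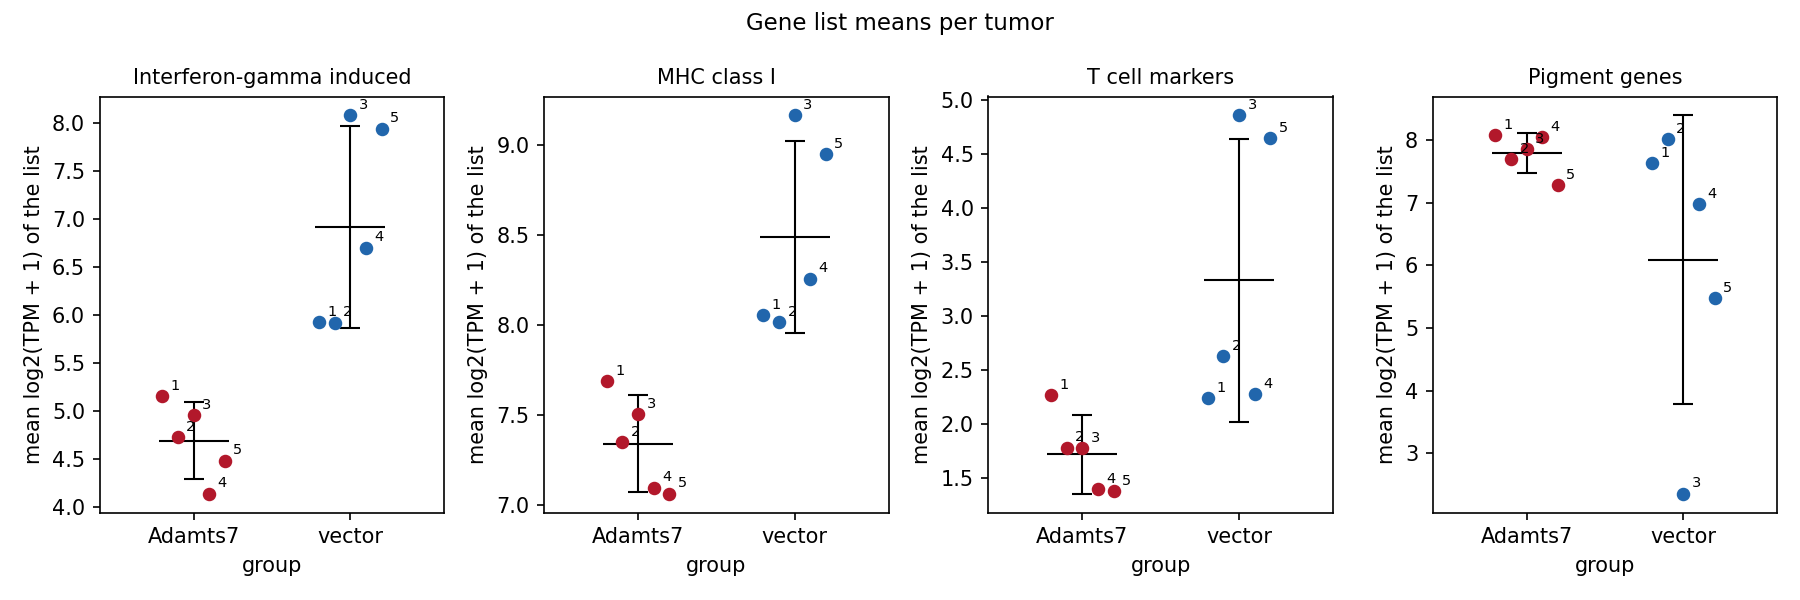
Mean log2(TPM + 1) of 4 gene lists (vertical axes) in each tumor of the 2 groups; points are tumors with their replicate numbers, bars the mean and SD of 5 tumors. The interferon-gamma list separates the groups, at 4.14 to 5.16 against 5.92 to 8.08, and vector tumors 3 and 5 lie apart from vector tumors 1, 2 and 4 in all 4 panels.

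Markers of T cells, cytotoxic lymphocytes, natural killer cells and dendritic cells were lower on average in Adamts7 tumors, most of all against vector tumors 3 and 5. In all 4 list means the groups overlapped. The highest Adamts7 tumor was at 2.27, 2.17, 1.84 and 2.75 log2(TPM + 1), in that order, and the lowest vector tumor at 2.24, 2.06, 1.47 and 2.41. All 14 T cell markers fell adjusted over the list alone and none over all genes, with a median log2 fold change of -1.59. Cd3e, a subunit of the T cell receptor complex, was at 3.23 ± 1.48 against 18.9 ± 16.6 TPM, and Cd8a, the CD8 coreceptor, at 2.02 ± 0.646 against 23.5 ± 25.8 TPM (SD, n = 5 each). Cd8a was at 62.8 and 37.2 TPM in vector tumors 3 and 5 and between 5.57 and 6.09 TPM in the other 3 vector tumors, against at most 2.98 TPM in an Adamts7 tumor. Ifng, which encodes interferon-gamma, was at 33.3 and 21.5 TPM in vector tumors 3 and 5, at most 4.52 TPM in the other 3, and at most 1.34 TPM in an Adamts7 tumor. Members falling adjusted over the list alone numbered 5 of 12 for cytotoxic lymphocytes, 9 of 9 for natural killer cells, where Klrd1 was at 2.10 ± 1.58 against 25.3 ± 27.9 TPM, and 5 of 11 for dendritic cells, where Irf8 was at 19.0 ± 6.76 against 65.8 ± 40.2 TPM. Camera called the 4 lists lower, with adjusted p-values from 1.4e-05 for T cells to 0.00286 for dendritic cells; all 4 had an adjusted p = 0.63 with an estimated correlation. Without vector tumors 3 and 5 the T cell median was -0.62. The cytotoxic, natural killer and dendritic cell medians went from -1.58, -1.71 and -1.02 to -0.59, -0.67 and -0.39 in that fit. None of the 4 lists passed fry there (adjusted p = 0.162 for T cells and cytotoxic lymphocytes, 0.228 for natural killer cells and 0.505 for dendritic cells). The dendritic cell call was lost there (camera adjusted p = 0.101); it was also lost without the tumor labelled Adamts7 5 (adjusted p = 0.0552), where the mean log2 fold change stayed about as large, -0.85 against -0.95.

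MHC class II genes, inhibitory checkpoint genes, lymphocyte-attracting chemokines and type I interferon induced genes were lower by the same test. Some lists share members and so are not separate results. Cxcl9 and Cxcl10 are in both the interferon-gamma and the chemokine list, and Cd274 is in both the interferon-gamma and the checkpoint list. Of the MHC class II list 7 of 10 fell adjusted over the list alone, including Ciita, its master regulator, at 3.63 ± 1.23 against 24.5 ± 17.7 TPM and H2-DMb1 at 44.8 ± 14.5 against 156 ± 72.8 TPM. Of the checkpoint list 7 of 12 fell adjusted over the list alone, with Pdcd1, which encodes PD-1, at 1.18 ± 0.682 against 11.2 ± 9.62 TPM, and of the chemokine list 5 of 11, with Cxcl9 at 15.5 ± 6.31 against 174 ± 165 TPM and Cxcl10 at 37.7 ± 12.7 against 354 ± 360 TPM (SD, n = 5 each). The type I interferon list had a median of -0.78 with 2 of 18 falling adjusted over the list alone; no member of these 4 lists fell over all genes. The camera adjusted p-values were 2.1e-05 for MHC class II, 0.000198 for checkpoints and 0.00131 for both chemokines and type I interferon. These calls were lost with an estimated correlation, at an adjusted p = 0.63 for the first 3 lists and 0.82 for type I interferon. Lists of inflammatory cytokine and NF-kB target genes and of complement genes (median -0.80) were also called lower, both at a camera adjusted p of 0.0133, with 0 members called in either; both had an adjusted p above 0.05 with an estimated correlation, 0.82 and 0.84. The camera direction of both turned without vector tumors 3 and 5, and the type I interferon call was lost there (mean -0.32 against -0.78). The type I interferon call was also lost without the tumor labelled Adamts7 5 (mean -0.59, camera adjusted p = 0.0716). So were the NF-kB target and complement calls, with means of -0.78 and -0.75 against -0.90 and -0.91 (camera adjusted p = 0.134 and 0.171). The MHC class II, checkpoint and chemokine medians went from -1.79 to -0.97, from -1.27 to -0.48 and from -1.82 to -0.70 without vector tumors 3 and 5. The checkpoint and chemokine calls were lost when the tumor labelled Adamts7 5 was left out with them (camera adjusted p = 0.120 and 0.214).

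By camera at the preset correlation, lists of pigment genes and of energy metabolism were higher in Adamts7 tumors. So were the mitochondrially encoded, immediate early and heat shock, and ribosomal protein lists, which were fixed beforehand as measures of quality. All 15 melanocyte differentiation genes had positive log2 fold changes with a median of 1.68, and 0 passed over all genes or over the list alone. The groups overlapped in the list mean, at 7.29 to 8.09 log2(TPM + 1) in Adamts7 tumors and 2.35 to 8.02 in vector tumors. The list did not pass fry (adjusted p = 0.269). Pmel, a melanosome protein, was between 3424 and 8390 TPM in the Adamts7 tumors, at 2431, 4380 and 1107 TPM in vector tumors 1, 2 and 4, and at 6.13 and 274 TPM in vector tumors 3 and 5. Hypoxia and glycolysis genes had a median log2 fold change of 0.53, with 15 of 16 positive and 0 called; Car9, a carbonic anhydrase induced by low oxygen, was at 112 ± 36.1 against 56.5 ± 23.6 TPM, and Pdk1 at 86.5 ± 19.8 against 56.4 ± 25.4 TPM (SD, n = 5 each). Mitochondrially encoded genes had a median of 0.37, with 6 of 10 rising adjusted over the list alone, and oxidative phosphorylation, immediate early and heat shock, and ribosomal protein genes had medians of 0.18, 0.15 and 0.11 with 0 called over the list alone. Camera called these 6 lists higher, with adjusted p-values from 1.4e-05 for hypoxia to 0.0268 for immediate early genes, and all 6 had an adjusted p = 0.63 with an estimated correlation. Quantile normalization, which moved the median log2 fold change of all genes from -0.10 to 0.04, kept 2 of the 6, pigment and hypoxia genes. Without the tumor labelled Adamts7 5 the oxidative phosphorylation, immediate early and ribosomal calls were lost, with mean log2 fold changes of 0.14, 0.14 and 0.08 against 0.15, 0.22 and 0.09 with all tumors (camera adjusted p = 0.0666, 0.164 and 0.0804). The pigment median was 0.37, the hypoxia median 0.12 and the oxidative phosphorylation median 0.10 without vector tumors 3 and 5. The hypoxia call was lost when the tumor labelled Adamts7 5 was left out with them (median 0.08, camera adjusted p = 0.159).

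As large a number of lists was also called in many splits that ignore the labels. Of 100 splits of the 10 tumors into 5 and 5, the real one included, 46 gave at least 12 lists in 1 direction. At least 6 were given by 77, but that sets the larger direction of each split against the smaller direction of the real one.

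**Figure D3:**
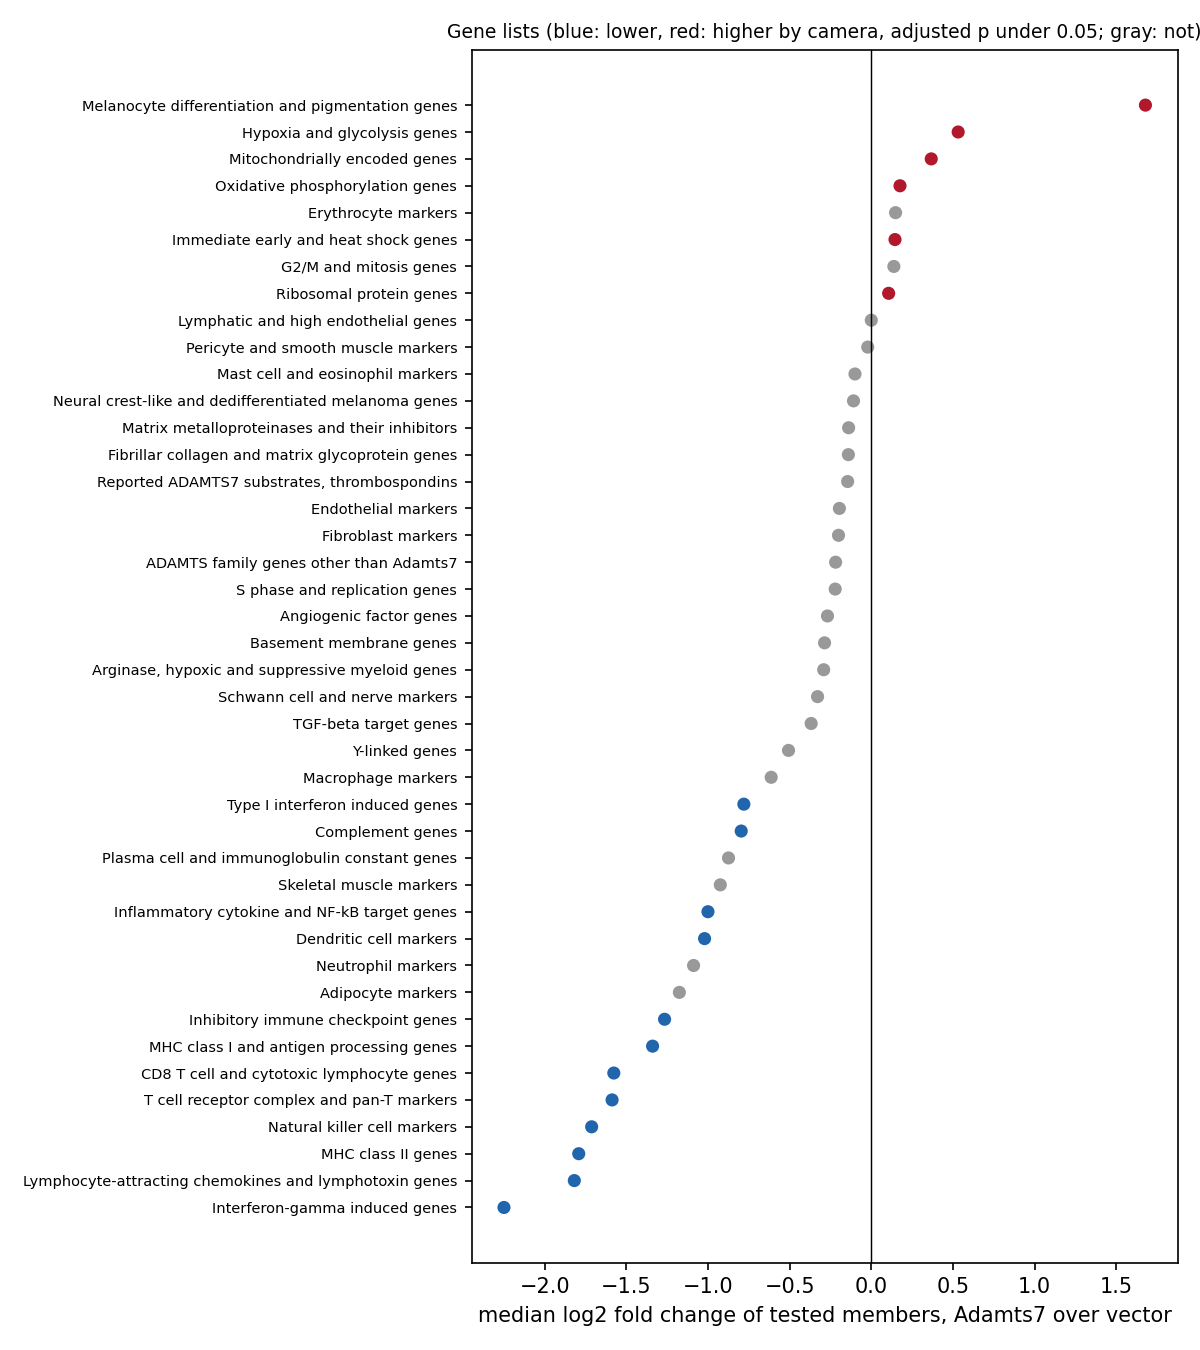
Median log2 fold change (horizontal axis, Adamts7 over vector) of the tested members of 42 gene lists, each a point; blue and red mark the 12 lists called lower and the 6 called higher by camera with a preset correlation, and gray the others. The interferon-gamma list has the lowest median, -2.25, and the pigment list the highest, 1.68.

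The extracellular matrix lists, among them reported ADAMTS7 substrates, did not pass with all 10 tumors. The substrate and thrombospondin list had a median log2 fold change of -0.14 with 4 of 8 members positive (camera adjusted p = 0.983); Ltbp1 was at 23.7 ± 9.02 against 38.9 ± 7.76 TPM and Thbs4 at 19.8 ± 8.94 against 9.44 ± 2.77 TPM (SD, n = 5 each). Fibrillar collagen genes had a median of -0.14 and fibroblast markers of -0.20, with Dcn at 31.8 ± 14.3 against 102 ± 90.2 TPM and Fap at 10.9 ± 4.42 against 6.58 ± 2.42 TPM. Camera, which compares a list with the other genes, placed these 3 lists above them although their medians were below 0. In the fit without vector tumors 3 and 5, chosen after the data were seen, camera called fibrillar collagen genes (median 0.29, adjusted p = 0.0407), fibroblast markers (median 0.29, adjusted p = 0.0211) and matrix metalloproteinases (median 0.21, adjusted p = 0.0032) higher. With the tumor labelled Adamts7 5 also left out it called the substrate list higher (median 0.48, adjusted p = 0.0355). None of these lists passed with an estimated correlation or by fry. Basement membrane genes had a median of -0.29 (camera adjusted p = 0.191), with Hspg2, which encodes perlecan, falling adjusted over the list alone from 207 ± 43.8 to 120 ± 21.3 TPM. Of 11 other ADAMTS family genes 4 fell adjusted over the list alone, among them Adamts1, at 274 ± 63.2 against 666 ± 312 TPM, and Adamts5, at 4.97 ± 0.855 against 20.8 ± 18.0 TPM (SD, n = 5 each), though the list did not pass (camera adjusted p = 0.322). Macrophage, endothelial, S phase and mitosis lists had medians of -0.61, -0.20, -0.22 and 0.14 and did not pass, with camera adjusted p-values of 0.396, 0.307, 0.729 and 0.0763. In the fit without vector tumors 3 and 5 the S phase list was called lower and its means did not overlap (median -0.33, camera adjusted p = 0.00192), and also with the tumor labelled Adamts7 5 left out (median -0.39). The mitosis list turned to called lower in the first of these fits (median -0.22, camera adjusted p = 0.0148) and in the second (median -0.24), and the macrophage list was called higher in the second (median 0.33, camera adjusted p = 0.0175). None of these calls held with an estimated correlation (adjusted p = 0.630 in the first fit and 0.824 in the second) or passed fry.

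T cell receptor repertoires were smaller in Adamts7 tumors. Distinct TRA clonotypes, the alpha chain sequences, numbered 6.20 ± 2.86 in Adamts7 tumors and 32.6 ± 27.4 in vector tumors, and distinct TRB clonotypes, the beta chain sequences, 7.40 ± 2.19 and 48.0 ± 38.9 (SD, n = 5 each). TRB clones numbered 9.20 ± 3.90 and 111 ± 117, and repertoire entropy was 2.37 ± 0.668 against 4.35 ± 0.924 bits for TRA and 2.76 ± 0.399 against 4.70 ± 0.733 bits for TRB. For these 5 of 20 measures all 5 Adamts7 tumors lay below all 5 vector tumors. The exact two-sided permutation p was 0.00794 for each, the smallest possible, and 0.0318 after Benjamini-Hochberg adjustment. A single measure at this p would not have passed over 20 measures. The 5 passed because they share it, and they are not separate results, as entropy follows the number of clonotypes. The deposited clone numbers do not count distinct sequences: Adamts7 tumor 3 has 9 heavy chain clones but 1 heavy chain clonotype. Added over TRA and TRB, clone numbers were 307 and 419 in vector tumors 3 and 5. They were between 37 and 43 in the other 3 vector tumors and between 8 and 26 in the Adamts7 tumors. Such a sum over 2 chains does not number T cells. The share of immunoglobulin heavy chains that were IgA, a mucosal isotype, was 0.0396 ± 0.0644 against 0.453 ± 0.283 (SD, n = 5 each) and did not pass (exact permutation p = 0.0238, adjusted p = 0.0794), nor did TRA clones (adjusted p = 0.113) or clonality and B cell receptor measures. The 5 measures still did not overlap between the groups without vector tumors 3 and 5, with at most 10 TRA and 9 TRB clonotypes in an Adamts7 tumor against at least 13 and 17. None of the 20 measures passed there, as 5 against 3 tumors allow no p below 0.0179. That is too high for 5 measures to pass after adjustment over 20. Leaving out 1 vector tumor kept 4 to 6 measures passing. Leaving out 1 Adamts7 tumor left 0 passing, with 3 or 4 at an unadjusted exact permutation p under 0.05, though the groups still did not overlap in the 5 measures.

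**Figure D4:**
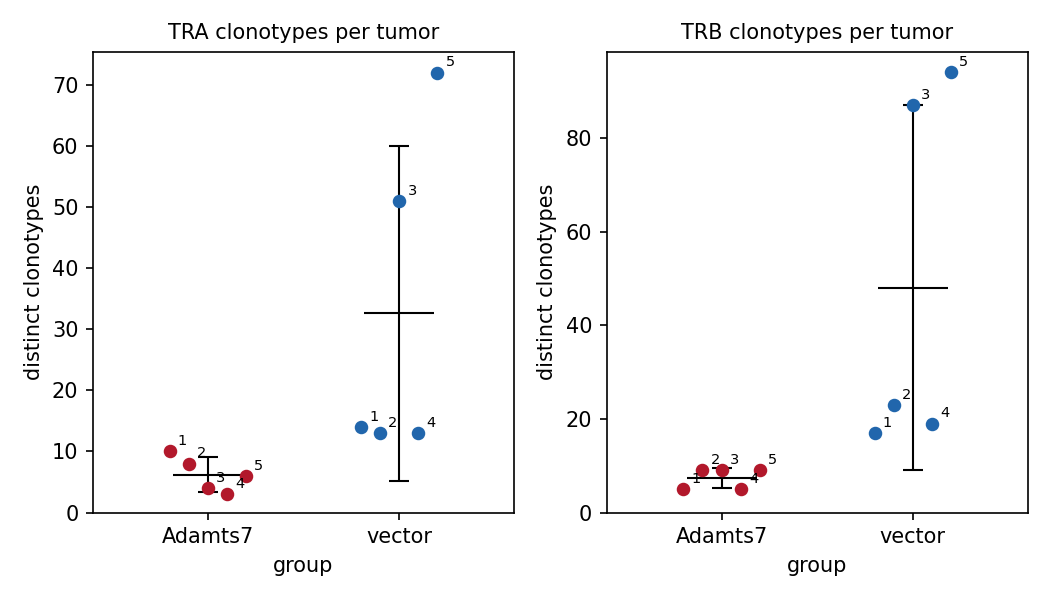
Number of distinct TRA and TRB clonotypes (vertical axes) in each tumor of the 2 groups; points are tumors with their replicate numbers, bars the mean and SD of 5 tumors. Every Adamts7 tumor lies below every vector tumor, with means of 6.20 against 32.6 TRA clonotypes and 7.40 against 48.0 TRB clonotypes.

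The authors' deposited table compares the same tumors and called more genes. It has 466 genes higher and 1030 lower at an adjusted p under 0.05, of 18796 genes with an adjusted p. The authors' deposited table gives Adamts7 a log2 fold change of 2.32 with an adjusted p of 0.000817, Gbp4 -3.46, Cxcl9 -3.36, Cd8a -3.42 and Gja3 4.71. Across 14492 genes in both, which are not independent replicates, its log2 fold changes and those of limma had Pearson's r of 0.871 and Spearman's rho of 0.980. Of 33 limma calls found in the authors' deposited table, 32 were called there in the same direction; of its 1220 calls among shared genes, 92.7% had an unadjusted limma p under 0.05. Both use the same libraries, so the overlap is not independent evidence.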

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

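The weighing of vector tumors 3 and 5, of the share of tumor cells in the tumor labelled Adamts7 5, and of those 2 vector tumors and of harvest day as the source of the interferon-gamma difference used tests chosen after the results were seen; the label test, the T cell adjustment and the splits of the tumors were written down before their results.

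A tumor far from the other 4 of its group was looked for in 232 groups of values and found in 7, where chance gives about 1 in 20, or 11.6. The tumor labelled Adamts7 5 accounted for 4 of the 7. It had Adamts7 at 18.2 TPM against 74.8 to 96.0 in the other 4 Adamts7 tumors. Its level of Atp5b, an ATP synthase subunit, was 1622 TPM against 2417 to 2632. Its hypoxia and glycolysis list mean was 7.70 against 7.01 to 7.18 log2(TPM + 1). Its share of IgG1 among heavy chains, of which it had only 24 clones, was 0.522 against 0 to 0.125. Adamts7 tumor 4 had Platr16 at 0.40 TPM against 1.11 to 1.39 TPM. Adamts7 tumor 1 had Iglc1 at 1.27 TPM while the other 4 are listed at 0. Vector tumor 4 had a skeletal muscle list mean of 5.56 against 0.31 to 0.76 in the other vector tumors.

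Whether the tumor labelled Adamts7 5 is a vector tumor under an Adamts7 label was not settled, as its values point both ways. On the 200 genes that best separated the other 9 tumors, where 0 is the vector mean and 1 the Adamts7 mean, it sat at 0.148, within the -0.282 to 0.488 of the vector tumors placed the same way, the range named in advance, and below the 0.744 to 1.10 of Adamts7 tumors 1 to 4. The vector positions used an Adamts7 mean that held this tumor, which limits the test. Other values follow its label. The interferon-gamma list mean was 4.48 (vector tumors 5.92 to 8.08), the MHC class I list 7.07 (8.02 to 9.17) and the T cell list 1.38 (2.24 to 4.86). It had 6 TRA and 9 TRB clonotypes (vector tumors at least 13 and 17). It lay with its group in all 34 called genes, with Gm3219 at 0 TPM (vector tumors 1.99 to 2.58 TPM). Those genes were chosen with it in its group. All 34 were also called without it, but among 655 genes called there. The 34 are calls that still passed with it added, so its place in them cannot decide its label. Its Y-linked median, which differed by -1.52 from the other 4 Adamts7 tumors, was at a level no vector tumor showed. Fewer tumor cells as the cause of its low Adamts7 and Y-linked transcripts are argued against, since its T cell, macrophage, fibroblast and endothelial lists all lay below the mean of the other 4, with -0.43 on the log2 scale as the difference closest to 0, while a wrong label, partial loss of the overexpression construct and biological variation within the group stay open. A first run compared the position with the vector median by a coding error and left the label undecided.

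Vector tumors 3 and 5 differed from the other vector tumors along the first principal component, which held 49.7% of the variance, with high lymphocyte genes and low pigment genes. The 4 Y-linked genes, which female hosts lack, argue against fewer tumor cells as the whole reason for the low pigment genes. They lay at a median of 0 and -0.0177 from the median vector tumor, within the spread of 0.244 of the others. Pigment genes lay at -5.29 and -1.66. Y-linked transcripts are an uncertain gauge of tumor cells. In the tumor labelled Adamts7 5 their median differed by -1.52 from the other Adamts7 tumors, while its host cell lists were lower too. The test of Y-linked against pigment genes took 3 forms. A first one averaged the 2 tumors, and a second asked for a pigment difference below -2 in each tumor. The second left the question undecided because of the -1.66. The present bound, the spread of the others, was set after that result, which weakens its answer against the explanation. Fewer tumor cells with an unchanged mix of host cells would raise all host markers alike. The T cell list rose beyond the endothelial list by 2.23 in vector tumor 3 and by 2.00 in vector tumor 5. In these 2 tumors the macrophage list rose by 1.37 and 1.20 and the fibroblast list by 1.00 and 0.86. The values argue only against an unchanged mix, as more T cells could go with fewer tumor cells. The rise of these lists, Xist at 39.2 and 34.6 TPM against 4.93 to 8.11 in the other vector tumors, and Sox10, a melanocyte lineage gene, at 269 and 311 TPM against 662 to 742 go with fewer tumor cells as a part of the cause, which stays open beside a loss of pigment gene expression together with more T cells, harvest day and tumor size.

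The lower interferon-gamma induced genes do not rest on vector tumors 3 and 5 alone, since the lowest of the other 3 vector tumors lay 0.76 above the highest Adamts7 tumor in the list mean. Nor did T cell content alone account for them in a linear model, where the group difference was -0.99 (SE 0.280) with the T cell list mean as a covariate and -2.22 without it, though the T cell list is an imprecise measure of T cells, which leaves part of that remainder open. Different harvest days are argued against as the whole cause, since in every 1 of the 100 possible sets of 3 against 3 tumors of day 45 the list median was below 0, at -1.21 or lower. An effect of Adamts7 overexpression stays open beside tumor size, which is given for no tumor and was not tested. The titles give only group and tumor number and name no separately made cells. Any other difference between the 2 injected cell populations goes with group and cannot be told apart from it. If the tumor labelled Adamts7 5 is a vector tumor, the list no longer separates the groups, because it lay at 4.48 there.

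Chance division of the tumors was examined over 100 splits into 5 and 5 drawn from all possible ones, the real one included. Where a direction is counted, the larger direction of a split was compared. For the 4 genes and the 6 lists that were higher, the smaller direction of the real split, this is not like against like. For the 34 called genes, 2 of the 100 splits gave as many. These were the real one and one that exchanged the tumor labelled Adamts7 5 with vector tumor 2, which gave 140. So large a count was uncommon among the splits, but chance is not excluded, since a split against the labels gave more. For the 4 genes that rose and the 30 that fell the count was 2 splits each, with 95 genes in 1 direction as the highest of the others. The exchanged split sets vector tumor 2 beside Adamts7 tumors 1 to 4, and after it and the real one the next highest split called 1 gene. Why it called more genes than the labels was not tested. For lists, chance cannot be excluded: 77 splits called at least 6 lists in 1 direction and 46 at least 12, with 28 as the highest of the other splits, so camera's counts at a preset correlation say little about the groups.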

How the results depend on the processing

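The fits without vector tumors 3 and 5, alone or with the tumor labelled Adamts7 5, were chosen after the data were seen; the other alternatives were planned. In every alternative the called genes it tested kept the sign of their log2 fold change. Against 4 genes higher and 30 lower in Adamts7 tumors, no filter on TPM gave 1 and 9, as more genes were tested, and a minimum of 5 TPM gave 2 and 26. Median-of-ratios scaling and quantile normalization gave 10 and 20 each; 24 of the 34 calls remained in each. Array weights, which give tumors far from their group less weight, gave 263 and 956. The replicate block gave 0 and 0 by limma, with 3028 genes at an unadjusted p under 0.05. The replicate numbers do not pair the tumors: correlations of same-numbered deviations were -0.278, 0.000865, 0.0471, 0.263 and -0.0331, and only the third tumors correlated best with their own number. Leaving out 1 tumor gave 0 to 171 genes higher and 5 to 484 lower, both maxima without the tumor labelled Adamts7 5. Without vector tumors 3 and 5 there were 2 and 26, with 10 of the 34 calls remaining, and additionally without the tumor labelled Adamts7 5 there were 197 and 603, with all 34 remaining. Over the 100 possible sets of 3 against 3 tumors of day 45 the medians were 0 and 0 by limma, with any gene higher in 23 sets and lower in 30. In all 100 Adamts7 was higher and camera with the preset correlation called the interferon-gamma and MHC class I lists lower; an estimated correlation, which ended both calls over all 10 tumors, was not run for these sets.

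The Adamts7 log2 fold change, 2.21, was 3.03 with array weights (limma adjusted p = 0.00517), 1.99 to 2.64 with 1 tumor left out, passing only without the tumor labelled Adamts7 5, and 3.36 without the 3 tumors that stood apart (limma adjusted p = 0.00014). Lists called higher numbered 2 under quantile normalization and 3 to 7 with 1 tumor left out, and lists called lower 8 to 13. An estimated correlation left 0 higher and 0 lower. Without vector tumors 3 and 5 the mean log2 fold change was -0.22 for G2/M genes, now lower, -0.12 for NF-kB targets and -0.13 for complement genes. Without the 3 tumors it was 0.27 for macrophage markers, now higher, -0.28 for G2/M genes, -0.0028 for NF-kB targets and 0.0391 for complement genes. With an estimated correlation no list was called in these 2 fits (adjusted p = 0.630 for G2/M genes in the first, 0.824 for G2/M genes and macrophage markers in the second). Lists called in neither fit changed direction in 89 cases. Repertoire measures passing numbered 5, against 0 by sign flips under the replicate block, where 0.0625 is the smallest possible p, 0 to 6 with 1 tumor left out, and 0 without vector tumors 3 and 5, where the smallest possible p of 0.0179 is too high for 5 measures to pass. Apart from the effects of more genes tested or fewer tumors, the cause was not tested. The unknown depth limits what low genes and small repertoires can show.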

Other observations

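Gm3219, Casp1, Batf2, Cd36 and Xist were picked for this part after their values were seen, as were the values per tumor, and no tests were added for them; the calls are those of the planned tests.

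Among genes of a dedifferentiated, neural crest-like melanoma state, Snai2, a transcription factor of cell migration, and Nt5e, which encodes the adenosine-producing enzyme CD73, fell adjusted over the list alone. Snai2 was at 5.63 ± 0.750 against 12.5 ± 4.30 TPM and Nt5e at 1.92 ± 1.12 against 14.3 ± 11.5 TPM (SD, n = 5 each), without overlap, and neither passed over all genes (limma adjusted p = 0.0840 and 0.0997). The list as a whole had a median log2 fold change of -0.11 and did not pass. Apln, an angiogenic peptide gene, rose adjusted over its list alone, at 40.0 ± 11.1 against 19.7 ± 5.71 TPM (SD, n = 5 each), and did not pass over all genes (limma adjusted p = 0.104).

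The predicted gene Gm3219 is listed at 0 in all 5 Adamts7 tumors and lay between 1.99 and 2.58 TPM in the 5 vector tumors. Casp1, the inflammatory caspase, was at 25.1 ± 4.71 against 67.2 ± 11.8 TPM, Batf2, an interferon-inducible transcription factor, at 27.2 ± 7.85 against 72.9 ± 15.2 TPM, and Cd36, a fatty acid receptor, at 4.14 ± 1.00 against 14.4 ± 5.05 TPM (SD, n = 5 each); all 3 fell over all genes.

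Xist, the noncoding RNA of the inactive X chromosome of female cells, was at 39.2 and 34.6 TPM in vector tumors 3 and 5 and between 2.77 and 10.5 TPM in the other 8 tumors. Ddx3y, a Y-linked gene, was at 3.97 TPM in the tumor labelled Adamts7 5 and between 15.3 and 24.1 TPM in the other 9. Ccl21a, a chemokine of lymphatic vessels, was at 48.3 and 397 TPM in vector tumors 4 and 5, at 3.78 TPM in vector tumor 2 and at most 0.47 TPM in every other tumor. IgA made up 62.5% and 78.1% of classified heavy chains in vector tumors 3 and 5 and 42.9% and 40.0% in vector tumors 2 and 4. It made up 2.94% in vector tumor 1 and at most 14.8% in an Adamts7 tumor. Some shares rest on few heavy chain clones, 16 each in vector tumors 2 and 4 and 9 and 6 in Adamts7 tumors 3 and 4.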
